A study of Mus musculus with 29 samples.

How the data were processed

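RNA from adult mouse right atrium and sinoatrial node was sequenced in wild-type libraries (WT) and in libraries titled Hom, whose genotype label names a deletion of a chromatin domain boundary at the locus that carries Pitx2. Per the labels the mice were at least 12 weeks old, the libraries were made with a KAPA mRNA HyperPrep kit, and sequencing was on an Illumina HiSeq instrument. The labels list 29 samples. The deposited tables hold 27 libraries, which were 6 WT and 6 Hom of right atrium and 8 WT and 7 Hom of sinoatrial node. Of the 8 WT right atrium samples in the labels, 3 titled F had no column of their own, and 1 WT F column carried a number that no title has. That column was used as an unnumbered WT F right atrium library, because its tissue, genotype and letter were clear. WT right atrium library F 1 was kept in right atrium by its title and source, although 1 of its characteristics names the sinoatrial node. The treatment protocol in the labels mentions left atria while the source name says right atrium, and title and source were followed here too. The titles do not say whether libraries of a group come from separate animals, so p-values measure the spread between the libraries as deposited.

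The authors deposited a table of normalised counts for each tissue. Per the labels the authors used STAR, DESeq2 and the mouse build mm10, with no versions given. The signal in the deposited tables is the number of reads per gene divided by a single size factor per library, computed by the authors separately for each tissue, so levels cannot be compared across tissues as deposited. Each column was checked for this scale. All values (100%) were within 0.01 of a whole multiple of the value of 1 read, and this gave back whole reads. The recovered totals ran from 13823743 to 27129008 reads per library. The tables hold 21079 genes, of which 20732 matched the RefSeq annotation by gene identifier. The sinoatrial node table also had 302 lines with a point in place of every value, and these were left out. The authors also deposited a table of called genes for each tissue with the mean signal, the log2 fold change by DESeq2, a standard error and a Wald statistic, each a score, and a p_value before and after adjustment by the authors. The sign of the authors' log2 fold changes was that of Hom against WT in the normalised counts, and the Wald statistic had the opposite sign in 100% of the lines.

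Genes were tested where the normalised count was 10 or more in at least 6 right atrium or 7 sinoatrial node libraries. This left 12576 and 13300 genes. Values were analysed as log2 of the normalised count plus 1 with limma 3.58.1 (eBayes with trend and robust settings) in R 4.3.3, with the letter F or M of the title as a covariate. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. Genes that passed are described as having risen or fallen, and fold changes are log2 of Hom over WT with the standard error of the fit. The difference between tissues was tested as the difference of the genotype effects, over 12512 genes tested in both tables. Differences between F and M were tested as the interaction of genotype and letter. Genes past the threshold in both tissues were counted and compared with chance by Fisher's exact test.

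Gene lists were fixed before the data were examined. They covered the neighbours of Pitx2 at the locus, genes reported for Pitx2, pacemaker genes, working atrium, ion channels and calcium handling, sarcomere, myocardial stress, oxidative phosphorylation, mitochondrially encoded genes, fatty acid oxidation, extracellular matrix, interferon response, immediate early genes, circadian clock and cell cycle. Marker lists covered endothelium, smooth muscle and mural cells, fibroblasts, epicardium, macrophages, lymphocytes, neurons, Schwann cells, erythroid cells, white and brown adipocytes, skeletal muscle, cartilage, lung and ventricle. Lists with at least 5 tested members were tested with limma camera at a preset correlation of 0.01, adjusted over the lists of the tissue. A list of sex-linked genes served only to check the letters, and reads from Y-linked genes matched them in all 27 libraries. Lists of ganglion neuron, MHC class II and heat shock genes were added after the results had been seen.

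The genes named in the text were set by a rule written before the data were examined. It takes Pitx2 and its neighbours, the 10 largest rises and 10 largest falls with a mean of 50 or more and the same sign among F and M, up to 4 members of each list with the lowest adjusted p, and 11 fixed genes. These 11 are Hcn4, Hcn1, Shox2, Isl1, Tbx3, Scn5a, Gja1, Gja5, Bmp10, Nppa and Ryr2. For the differences between tissues and between letters the 5 largest of each sign were taken. Members of the added lists and the gene Cpne5, named in the closing part, were chosen after their values were seen.

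Alternatives were a pseudocount of 0.5 or 5, other filters, rescaling by TMM factors or upper quartile, edgeR 4.0.16 and DESeq2 1.42.0 on whole reads, library weights, a replicate block by letter and number, no letter term, either letter alone and leaving out each library. The lists were also tested with an estimated correlation and with fry. Alternatives chosen after the data were seen left out 4 right atrium libraries with over 75% mitochondrial reads or the 3 WT F libraries, added the mitochondrial share as a covariate, or tested the lists within a letter. Chance was assessed with 100 splits of the libraries, the real one included. The tests were also checked on simulated data with planted changes. A planted 2-fold change was recovered for 53.7% of genes in right atrium and 76.1% in sinoatrial node. For the difference between tissues it was 41.8%, and between F and M 1.5% in right atrium and 28.4% in sinoatrial node. The simulated genes varied independently, so structure that genes of a library share was not simulated. Confidence intervals of read counts are exact Poisson intervals at 95%, the floor of a count of 0 is 3 reads, and both cover counting error only. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and drew the figures.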

Results

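RNA was sequenced from adult mouse right atrium and from the sinoatrial node, the pacemaker region of the heart. Mice with a deletion of a boundary between chromatin domains near Pitx2 (Hom) were compared with wild-type mice (WT). The right atrium had 6 WT libraries (3 F, 3 M) and 6 Hom libraries (3 F, 3 M). The sinoatrial node had 8 WT libraries (4 F, 4 M) and 7 Hom libraries (3 F, 4 M). Depth ran from 13823743 to 27129008 reads per library. The question put to each tissue was which genes differ between Hom and WT, starting with the genes next to the deleted boundary.

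Pitx2, a transcription factor that sets left-sided identity in the heart, lies on mouse chromosome 3 from 129199878 to 129219594 (mm10; ENSMUSG00000028023, protein-coding). Its normalised count in the sinoatrial node was 18.9 ± 13.3 (SD, n = 8) in WT and 71.6 ± 38.8 (SD, n = 7) in Hom. It rose by 2.37 ± 0.53 (SE) on the log2 scale, with an adjusted p of 0.00357 by limma. All 7 Hom libraries were above the WT mean, and the log2 difference was 1.45 among F and 3.15 among M libraries. WT library M 4 had 0 reads, and the other WT libraries had 6 to 42 reads. The Hom libraries had 14 to 138 reads. In the right atrium, Pitx2 had 0 reads in the 6 WT libraries together, which held 114150909 reads. The floor of 3 reads is 0.0263 CPM there, and the exact Poisson upper limit is 0.0323 CPM at 95%. The 6 Hom libraries together had 8 reads, 0.0643 CPM (0.0278 to 0.127), and all of them came from 2 libraries. An exact permutation test over 924 splits, two-sided, gave p = 0.455, the smallest p it can give with reads in 2 libraries, so whether Pitx2 differs in the right atrium stays open. Intervals and floors cover counting error only.

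**Figure D1:**
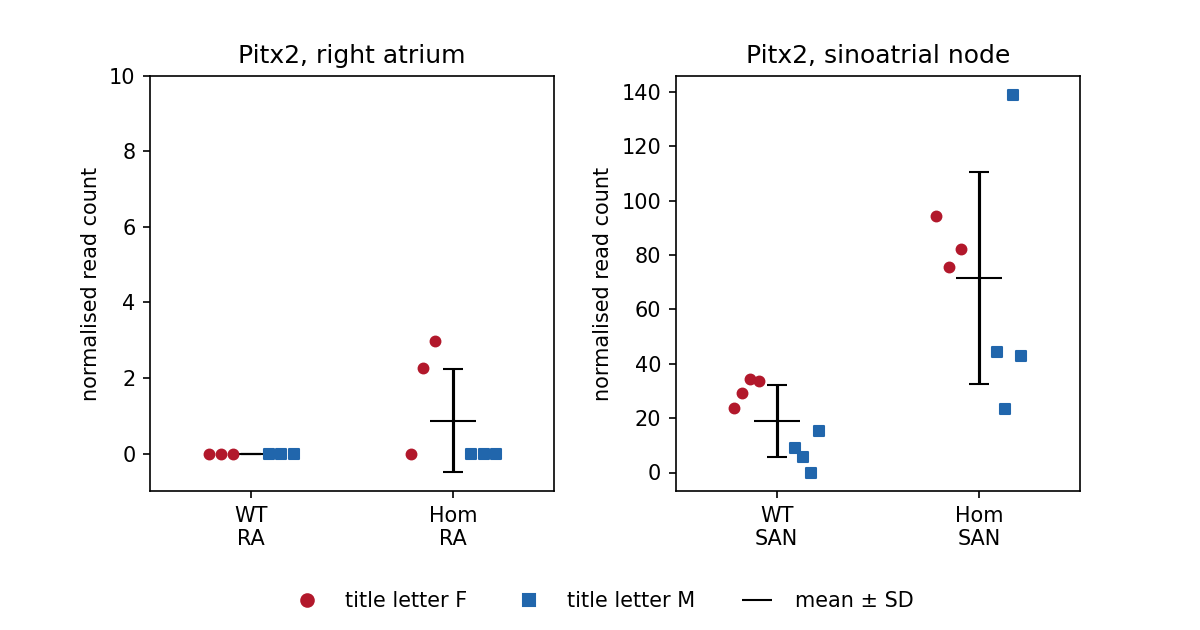
Pitx2 in each library of right atrium and sinoatrial node, as normalised counts on the vertical axis, with a point per library and the mean and SD of WT and Hom. The sinoatrial node mean was 18.9 in WT and 71.6 in Hom, and in the right atrium 4 of 6 Hom libraries and all 6 WT libraries were at 0 (the vertical scales differ).

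Few neighbours of Pitx2 at the locus passed the threshold in the sinoatrial node. There, 15 of the 23 genes of the locus list were tested, and 2 rose (2 adjusted over the list alone), Pitx2 and Larp7. At an unadjusted p under 0.05 there were 6, these 2 included. Elovl6, Casp6 and Ccdc109b did not pass, but each had 0 of 7 Hom libraries above the WT mean. Larp7, which encodes a protein that binds the 7SK small nuclear RNA, rose by 0.32 ± 0.10 (SE) with an adjusted p of 0.0365, and 6 of 7 Hom libraries were above the WT mean. Leaving out Hom F 1, F 2, F 4, M 1 or M 6, or WT M 1, F 2, F 3 or F 4, ended that call, with adjusted p from 0.0565 to 0.0755. The median of the locus list was −0.04, camera put its direction upwards, and the list did not pass (adjusted p = 0.976). By fry (mixed), which counts moves in both directions, the list with Pitx2 in it passed (adjusted p = 1.02e-05). In the right atrium 14 locus genes were tested by limma and 0 passed (0 adjusted over the list alone), with 4 at an unadjusted p under 0.05. edgeR also called 0, and DESeq2 called 2 lower. The lowest adjusted p of a named neighbour was that of Tifa, an adaptor protein of NF-kB signalling, at −0.89 ± 0.26 (SE) and 0.125. Tifa passed by DESeq2 (adjusted p = 0.011) and, with limma, without the 4 libraries with over 75% mitochondrial reads (−1.17, adjusted p = 0.0283). The list median there was −0.24 (adjusted p = 0.349).

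Reads from mitochondrial genes took very different shares of the libraries. In the right atrium they made up 81.1% ± 2.88 (SD, n = 3) of the reads of WT F libraries and 41.1% ± 5.65 (SD, n = 3) of WT M libraries. Hom F libraries had 41.2% ± 10.9 (SD, n = 3) and Hom M libraries 61.1% ± 14.1 (SD, n = 3), where library M 3 reached 77.1%. The 3 WT F libraries and Hom M 3 were the 4 libraries over 75%. The sinoatrial node shares were 25.1% ± 7.22 (SD, n = 4) in WT F and 34.2% ± 7.82 (SD, n = 3) in Hom F. M libraries had 40.5% ± 11.2 (SD, n = 4) in WT and 52.0% ± 4.78 (SD, n = 4) in Hom. The share thus moved with genotype and letter in the right atrium. Values without those 4 libraries are given for the lists that passed there and for part of the named genes. Of 36 right atrium genes followed without them, 25 kept direction and call, 2 lost the call, 5 gained it and 4 changed sign. Tests of the fixed lists in that set and within a letter used the preset correlation alone. That set held 3 WT libraries, all M, and 5 Hom libraries, and it was chosen after the data were seen. With the letter as a covariate and no WT F library left, its fold changes compare 2 Hom M with 3 WT M libraries, and the 3 Hom F libraries add only to the estimate of spread.

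**Figure D2:**
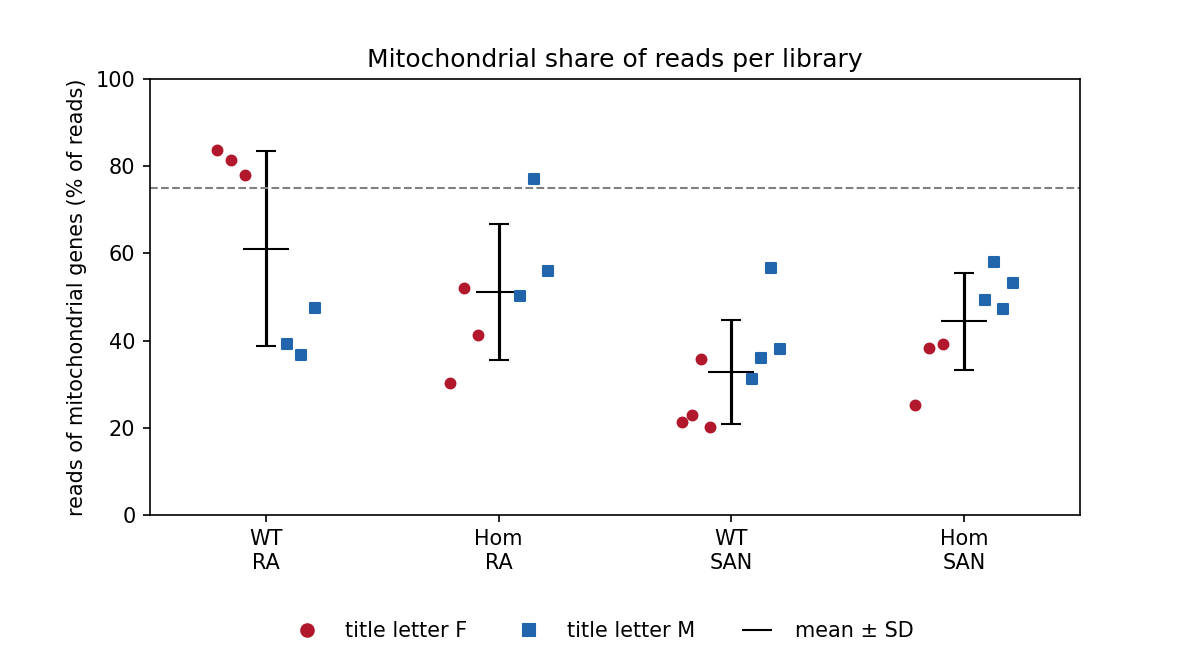
Share of each library's reads that fell on mitochondrially encoded genes, in percent, by tissue, genotype and title letter, with a point per library. The 3 WT F right atrium libraries lie between 78.1% and 83.8%, and Hom M 3 of right atrium lies at 77.1%.

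In the right atrium, markers of the epicardium, the cell layer that covers the heart, fell together in Hom. Krt19, a keratin of simple epithelia, went from a normalised count of 310 ± 38.6 (SD, n = 6) in WT to 83.3 ± 19.6 (SD, n = 6) in Hom, and fell by 1.91 ± 0.19 (SE, adjusted p = 0.000677 by limma). Msln, the surface protein mesothelin, fell by 1.90 ± 0.20 (SE, adjusted p = 0.00092), and the uroplakin Upk1b fell by 1.91 ± 0.21 (SE, adjusted p = 0.00105). All 6 Hom libraries lay below the WT mean for these 3 genes. Of the 6 markers tested, 4 fell (5 adjusted over the list alone), and the list median was −1.79 (camera adjusted p = 1.09e-09). With an estimated correlation the list had an adjusted p = 0.0754, and without the 4 libraries with over 75% mitochondrial reads its median was −1.77 (adjusted p 1.1e-12). The fourth to fall, the uroplakin Upk3b, fell by 1.68 ± 0.30 (SE, adjusted p = 0.0179), and its call ended without WT M 5 (adjusted p 0.0528) or WT F 2 (adjusted p 0.0584). The WT mean in this group includes 3 libraries with over 75% mitochondrial reads. Without the 4 such libraries Krt19 was at −1.82 (adjusted p 0.00015), Msln at −1.64 (adjusted p 6.08e-06), Upk1b at −1.73 (adjusted p 1.2e-05) and Upk3b at −1.99 (adjusted p 1.01e-08).

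Other large falls in the right atrium included Lrrn4, a leucine-rich repeat membrane protein, which fell by 2.23 ± 0.30 (SE, adjusted p = 0.00336). Ckmt1, a mitochondrial creatine kinase, fell by 2.25 ± 0.34 (SE, adjusted p = 0.00771), and Inmt, an indolethylamine N-methyltransferase, fell by 2.34 ± 0.35 (SE, adjusted p = 0.00648). Each was below the WT mean in 6 of 6 Hom libraries. Among the rises were Hbb-bs, a beta globin, at 1.48 ± 0.21 (SE, adjusted p = 0.00451), and the heat shock protein Hsph1 at 0.97 ± 0.13 (SE, adjusted p = 0.00275). The transcription factors Klf15 and Klf2 rose by 1.11 ± 0.17 (SE) and 1.01 ± 0.16 (SE), with an adjusted p of 0.00809 for both. All 6 Hom libraries were above the WT mean for these 4 genes. Without the 4 libraries with over 75% mitochondrial reads these 7 genes kept their direction and their call, from −1.60 for Lrrn4 to 1.18 for Hbb-bs. Inmt was then at −0.97, and its adjusted p was 0.0135.

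Across the right atrium 46 genes rose and 60 fell, 106 of 12576 tested. A further count at an unadjusted p under 0.05 gave 2196 genes. The count depended on single libraries. It was 39 without Hom F 7 or WT M 5, 44 without Hom F 4, 46 without Hom F 3, 52 without WT M 1 or WT F 2, 58 without Hom M 5 and 59 without WT M 4. It was 311 without Hom M 3. Without the 4 libraries with over 75% mitochondrial reads 998 genes passed, 426 higher and 572 lower, in what is a comparison of 2 Hom M with 3 WT M libraries, and 90 of the 106 were among them. DESeq2 called 688 genes on the same libraries, with all 106 among them.

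Metabolic and vessel lists of the right atrium passed camera with the preset correlation and did not pass with an estimated one. Of 19 oxidative phosphorylation genes 1 rose (1 adjusted over the list alone), with a list median of 0.23 (camera adjusted p = 0.00287, and adjusted p = 0.558 with an estimated correlation). That gene was Uqcrc2, a core subunit of respiratory complex III, at 0.63 ± 0.14 (SE, adjusted p = 0.0453). Of 18 fatty acid oxidation genes 2 rose (5 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.00287, and adjusted p = 0.193 with an estimated correlation). These were Etfdh, which passes electrons to ubiquinone, at 0.67 ± 0.14 (SE, adjusted p = 0.0362), and the fatty acid carrier Fabp3 at 0.64 ± 0.13 (SE, adjusted p = 0.0376). Of 8 endothelial markers 1 rose (4 adjusted over the list alone), with a median of 0.62 (camera adjusted p = 0.00118, and adjusted p = 0.298 with an estimated correlation). It was Vwf, von Willebrand factor, at 0.80 ± 0.15 (SE, adjusted p = 0.0221). Leaving out any library except Hom M 3 ended the calls of Uqcrc2 (adjusted p 0.0575 to 0.141) and Fabp3 (adjusted p 0.0551 to 0.123). For Etfdh any library except Hom M 1, Hom M 3 and WT F 1 did (adjusted p 0.0589 to 0.118), and for Vwf each of Hom F 3, F 4 and F 7 and WT M 5 and F 2 did (adjusted p 0.0528 to 0.0788). Without the 4 libraries with over 75% mitochondrial reads the endothelial list did not pass (median 0.11, adjusted p = 0.331), while oxidative phosphorylation (adjusted p 1.06e-07) and fatty acid oxidation (adjusted p 1.16e-08) did. The endothelial markers followed in that set disagreed. Cdh5 was at −0.74 (adjusted p 0.00232) and Kdr at −0.44 (adjusted p 0.0261), while Vwf was at 0.58 (adjusted p 0.00166) and Pecam1 at 0.06 (adjusted p 0.736).

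Macrophage markers had a median of −0.43 in the right atrium and a camera adjusted p = 0.00544. With an estimated correlation the adjusted p was 0.15, and without the 4 libraries with over 75% mitochondrial reads the median was −0.55 (camera adjusted p 4.68e-06). Of the 7 markers tested by limma 0 passed over all genes, 2 fell adjusted over the list alone, and 4 had an unadjusted p under 0.05. edgeR called 0 of them and DESeq2 called 2 lower. The scavenger receptor Cd163 was at −0.96 ± 0.23 (SE, adjusted p = 0.0685), and it passed without Hom M 3 (−1.13, adjusted p 0.016).

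Pacemaker genes did not move as a group in the right atrium. Of 15 tested 1 rose and 1 fell (1 and 3 adjusted over the list alone), the median was 0.06 with camera pointing down, and the list did not pass (adjusted p = 0.65). Popdc2, a membrane protein that binds cyclic AMP, rose by 0.63 ± 0.13 (SE, adjusted p = 0.0339), and Ntm, a neuronal adhesion protein, fell by 1.46 ± 0.30 (SE, adjusted p = 0.0365). Leaving out any library except Hom M 3 ended the Popdc2 call (adjusted p 0.0536 to 0.104), and any except Hom M 1 and M 3 ended the Ntm call (adjusted p 0.0551 to 0.116). Tbx18, a transcription factor of the node and epicardium, was at −1.25 ± 0.29 (SE, adjusted p = 0.0587), and it passed without Hom M 3 (−1.49, adjusted p 0.00966). Hcn4, Hcn1 and Isl1 were below the filter. Without the 4 libraries with over 75% mitochondrial reads Ntm was at −0.43 (adjusted p 0.335) and Tbx3, a repressor of the working atrial programme, was at −1.31 ± 0.24 (SE, adjusted p = 0.00216). With all libraries Tbx3 was at −0.71 ± 0.33 (SE, adjusted p = 0.284).

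Working atrial genes of the right atrium did not pass as a list with all libraries together (18 tested by limma, 0 passed, 1 adjusted over the list alone, 5 at an unadjusted p under 0.05, median 0.04, adjusted p = 0.363). The list passed without the 4 libraries with over 75% mitochondrial reads (median 0.30, adjusted p 1.13e-07) and among M alone (median 0.34, adjusted p 8.95e-06), and among F its median was −0.07 (adjusted p 0.294). edgeR called 0 of them and DESeq2 called 1. Bmp10, an atrial growth factor, was at −0.67 ± 0.39 (SE, adjusted p = 0.377), and Ryr2, the calcium release channel, was at −0.45 ± 0.26 (SE, adjusted p = 0.379). Both turned without the 4 libraries with over 75% mitochondrial reads, to 0.54 (adjusted p 0.0038) and 0.41 (adjusted p 0.0102). The sodium channel Scn5a was at 0.60 ± 0.13 (SE, adjusted p = 0.0547), and it passed without Hom M 3 (0.64, adjusted p 0.0311). The natriuretic peptide gene Nppa was at 0.38 ± 0.17 (SE, adjusted p = 0.27). The connexins Gja1 and Gja5 were at −0.56 ± 0.27 (SE, adjusted p = 0.294) and −0.19 ± 0.17 (SE, adjusted p = 0.575), and without those 4 libraries at 0.19 (adjusted p 0.39) and 0.18 (adjusted p 0.359). Of 20 sarcomere genes 1 rose (1 adjusted over the list alone), the cardiac actin Actc1, at 0.74 ± 0.16 (SE, adjusted p = 0.0452). The sarcomere list had a median of 0.07 (adjusted p = 0.301) and passed without those 4 libraries (median 0.26, adjusted p 3.68e-06). Leaving out any library except Hom M 3 ended the Actc1 call (adjusted p 0.0605 to 0.141).

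The remaining right atrium lists did not pass with all libraries together. Without the 4 libraries with over 75% mitochondrial reads 4 of them did. These were extracellular matrix (median −0.44, adjusted p 7.07e-07), ion channels and calcium handling (0.26, 5.43e-05), fibroblast markers (−0.35, 0.000226) and mitochondrially encoded genes (0.78, 0.00213). The last had a median of −3.01 among F (adjusted p 0.000442) and 1.31 among M (adjusted p 2.34e-05). Of 25 extracellular matrix genes 1 rose (1 higher and 1 lower adjusted over the list alone), the cartilage matrix protein Comp, at 0.93 ± 0.14 (SE, adjusted p = 0.00597), with a list median of −0.04 (adjusted p = 0.301). Of 14 interferon response genes 1 fell (1 adjusted over the list alone), Oasl2, at −0.91 ± 0.16 (SE, adjusted p = 0.0183), with a median of −0.21 (adjusted p = 0.146). Its call ended without Hom F 3 (adjusted p 0.0572), Hom F 7 (adjusted p 0.0694) or WT M 5 (adjusted p 0.0654). For 10 further lists limma called 0 members over all genes. These were ion channels and calcium handling (30 tested, 2 adjusted over the list alone, adjusted p = 0.287) and circadian clock (14, 2, 0.3). Myocardial stress (12, 1, 0.3), genes reported for Pitx2 (12, 0, 0.3) and cell cycle (10, 0, 0.301) were others. The rest were immediate early genes (14, 0, 0.086), mitochondrially encoded genes (8, 0, 0.115), smooth muscle and mural markers (7, 0, 0.301) and fibroblast markers (8, 0, 0.65). Skeletal muscle markers (5, 0, 0.486) came last. At an unadjusted p under 0.05 these lists had 7, 6, 5, 2, 2, 2, 0, 1, 1 and 0 members in the same order. edgeR called 0 in each, and DESeq2 called 3 ion channel, 2 circadian and 3 stress genes and 0 in the others. Lists with under 5 tested members were not run. Of these, erythroid markers had 2 of 3 members that rose, and brown adipocyte (3 tested), cartilage (2), lung (1), lymphocyte (3), neuron (2), Schwann (4) and ventricle (4) markers had 0. At an unadjusted p under 0.05, cartilage and lung had 1 each, edgeR called 0 and DESeq2 called 1, in lung. No white adipocyte marker was tested.

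In the sinoatrial node, genes of the pacemaker programme fell in Hom. Hcn4, the main channel of the pacemaker current, went from 79.3 ± 22.6 (SD, n = 8) in WT to 35.7 ± 25.7 (SD, n = 7) in Hom, and fell by 1.45 ± 0.42 (SE, adjusted p = 0.0196 by limma). Tbx3 fell by 0.63 ± 0.12 (SE, adjusted p = 0.00115), and Cacna1g, a T-type calcium channel, fell by 0.53 ± 0.12 (SE, adjusted p = 0.00407). Isl1, a transcription factor of node cells and of autonomic neurons, fell by 2.97 ± 0.77 (SE, adjusted p = 0.0102). All 7 Hom libraries were below the WT mean over both letters for these 4 genes. For Isl1, Hom F 2 (normalised count 25.5) was above the WT F libraries (14.4 to 19.4). Of 18 pacemaker genes 8 fell (9 adjusted over the list alone), 0 rose, and the median was −0.37 (camera adjusted p = 0.00173, and adjusted p = 0.0151 with an estimated correlation). Shox2 at 0.06 ± 0.16 (SE, adjusted p = 0.833) and Hcn1 at −0.14 ± 0.32 (SE, adjusted p = 0.817) did not pass, and their signs turned without WT F 2 (−0.02) and Hom F 1 (0.05). Isl1 was at −0.19 among F and −5.36 among M libraries, Hcn4 at −0.56 and −2.22, and Tbx3 at −0.30 and −0.91. None of them passed among F alone (adjusted p 0.889, 0.398 and 0.283). Cacna1g was at −0.53 among F and −0.52 among M. By edgeR the adjusted p of Hcn4 was 0.0526. Within a letter the list passed among M (median −0.39, adjusted p = 0.000188) and did not pass among F (median −0.25, adjusted p 0.118).

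**Figure D3:**
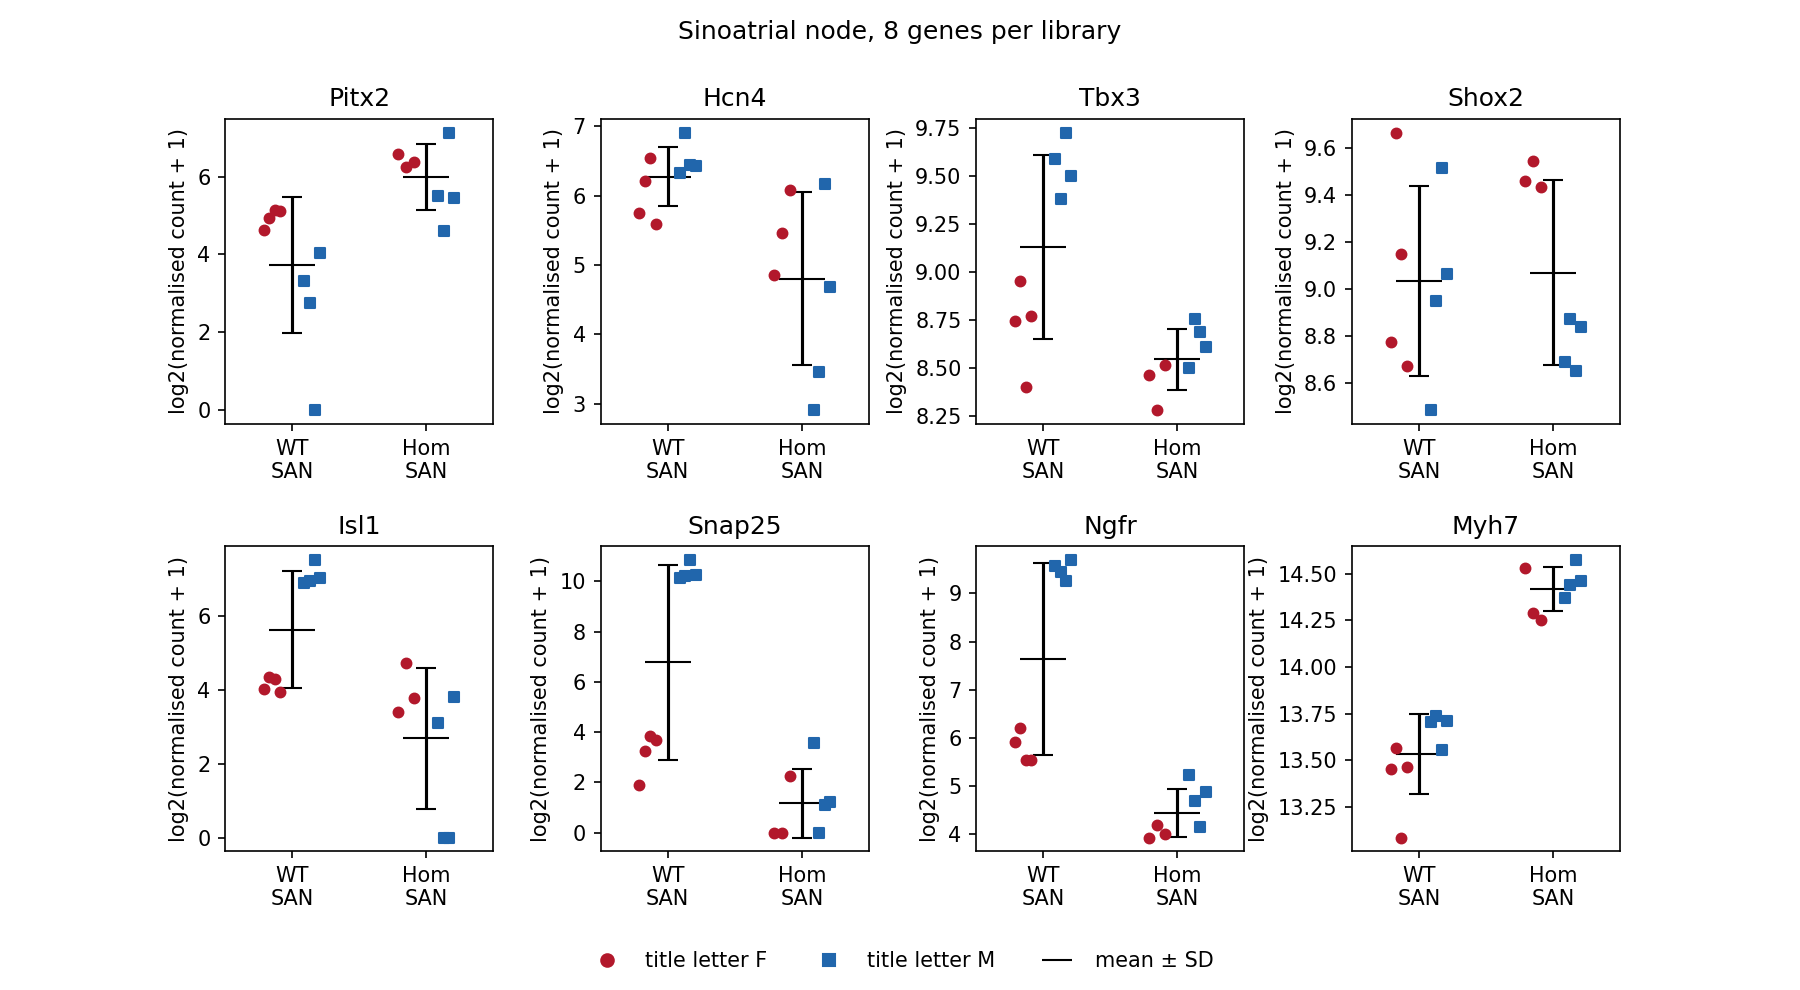
Levels of 8 genes in each sinoatrial node library as log2 of the normalised count plus 1 on the vertical axis, with a point per library by title letter and the mean and SD of WT and Hom. The fall of Isl1 (−0.19 among F, −5.36 among M) and Snap25 (−2.43 among F, −8.91 among M) stands against WT M libraries that lie above the WT F libraries.

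Neuron and Schwann cell markers also fell in the sinoatrial node, most among M libraries. Snap25, a protein of synaptic vesicle release, went from 679 ± 749 (SD, n = 8) to 2.43 ± 3.94 (SD, n = 7), and fell by 5.92 ± 0.87 (SE, adjusted p = 9.79e-05). Ddc, an enzyme of catecholamine synthesis, fell by 3.83 ± 0.99 (SE, adjusted p = 0.0124), and Prph, a peripheral neuron filament, fell by 3.39 ± 0.97 (SE, adjusted p = 0.0315). Of 7 neuron markers 5 fell (7 adjusted over the list alone), with a median of −1.77 (camera adjusted p = 1.28e-05, and adjusted p = 0.0905 with an estimated correlation). Of 6 Schwann markers 5 fell (5 adjusted over the list alone), with a median of −1.11 (camera adjusted p = 1.12e-05, and adjusted p = 0.0905 with an estimated correlation). Ngfr, a neurotrophin receptor, fell by 3.36 ± 0.38 (SE, adjusted p = 3.6e-06), and Sox10, a glial transcription factor, fell by 1.33 ± 0.20 (SE, adjusted p = 0.000129). The log2 difference of Snap25 was −2.43 among F and −8.91 among M libraries, that of Prph 0.18 and −6.44, and that of Sox10 −0.69 and −1.87. The neuron list passed among M (adjusted p = 5.42e-17) and did not pass among F (adjusted p 0.917). The Schwann list likewise passed among M (median −1.67, adjusted p 1.04e-11) and did not pass among F (median −0.46, adjusted p 0.11). The Prph call ended without Hom M 1 (adjusted p 0.0554), M 2 (adjusted p 0.0536) or M 4 (adjusted p 0.0624) or WT M 4 (adjusted p 0.0574), and by edgeR (adjusted p 0.0513). Leaving out 1 library moved the fold of 2 genes by over 1.5 times. Ddc was at −4.45, −4.46, −3.22 and −4.49 without Hom F 2, Hom F 4, Hom M 2 and WT F 1, and Snap25 at −6.62 without Hom F 4.

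Genes of stressed and remodelling heart muscle rose in the sinoatrial node. Myh7, the slow myosin heavy chain of fetal and stressed heart, went from 11979 ± 1637 (SD, n = 8) to 21942 ± 1801 (SD, n = 7), and rose by 0.87 ± 0.08 (SE, adjusted p = 1.29e-07). Acta1, skeletal actin, rose by 1.25 ± 0.24 (SE, adjusted p = 0.000974), and the stretch-responsive Ankrd1 rose by 0.53 ± 0.09 (SE, adjusted p = 0.000238). Of 13 myocardial stress genes 8 rose (10 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 1.33e-07, and adjusted p = 0.00216 with an estimated correlation). Of 21 sarcomere genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.00325, and adjusted p = 0.329 with an estimated correlation). Mybpc3, a thick filament protein, rose by 0.37 ± 0.07 (SE, adjusted p = 0.00121), and the light chain Myl1 fell by 0.50 ± 0.09 (SE, adjusted p = 0.00035). Of 18 working atrium genes 4 rose and 2 fell (4 and 2 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.0436, and adjusted p = 0.531 with an estimated correlation). Bmp10 rose by 0.90 ± 0.15 (SE, adjusted p = 0.000263) and Ryr2 by 0.42 ± 0.07 (SE, adjusted p = 0.000338). Scn5a rose by 0.34 ± 0.09 (SE, adjusted p = 0.00851), and the potassium channel Kcna5 fell by 0.68 ± 0.17 (SE, adjusted p = 0.00833). Among F libraries alone the working atrium list pointed down (median −0.14, adjusted p = 0.0925). The sarcomere list did not pass among F (median −0.05, adjusted p 0.877) and passed among M (median 0.25, adjusted p 5.75e-07). Nppa was at 0.20 ± 0.10 (SE, adjusted p = 0.213), Gja5 at −0.21 ± 0.16 (SE, adjusted p = 0.393) and Gja1 at 0.03 ± 0.09 (SE, adjusted p = 0.872), which was −0.02 without Hom F 4.

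Markers of blood vessels fell in the sinoatrial node. Cdh5, the cadherin of endothelial junctions, went from 1564 ± 223 (SD, n = 8) to 688 ± 211 (SD, n = 7), and fell by 1.28 ± 0.11 (SE, adjusted p = 3.14e-08). The smooth muscle actin Acta2 fell by 1.04 ± 0.08 (SE, adjusted p = 1.02e-08), and Tagln, an actin-binding protein of smooth muscle, fell by 0.52 ± 0.09 (SE, adjusted p = 0.000338). All 7 Hom libraries were below the WT mean for these 3 genes. Of 8 endothelial markers 4 fell (5 adjusted over the list alone), with a median of −0.33 (camera adjusted p = 3.9e-05, and adjusted p = 0.00873 with an estimated correlation). Of 7 smooth muscle and mural markers 4 fell (5 adjusted over the list alone), with a median of −0.52 (camera adjusted p = 1.28e-05, and adjusted p = 0.00406 with an estimated correlation). Vwf fell by 0.51 ± 0.09 (SE, adjusted p = 0.000454). Epicardial markers fell here too, 2 of 6 (4 adjusted over the list alone), with a median of −0.54 (camera adjusted p = 0.019, and adjusted p = 0.0877 with an estimated correlation). Upk3b fell by 0.74 ± 0.17 (SE, adjusted p = 0.00445) and Krt19 by 0.64 ± 0.19 (SE, adjusted p = 0.0216). The Krt19 call ended without WT M 3 (adjusted p 0.052) or WT M 5 (adjusted p 0.057).

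Cell cycle and mitochondrially encoded genes were higher in the sinoatrial node of Hom. Of 11 cell cycle genes 3 rose (3 adjusted over the list alone), with a median of 1.10 (camera adjusted p = 0.00173, and adjusted p = 0.11 with an estimated correlation). Birc5, a regulator of cell division, rose by 1.97 ± 0.49 (SE, adjusted p = 0.00793), and the proliferation marker Mki67 rose by 1.33 ± 0.39 (SE, adjusted p = 0.0238). Top2a, which untangles DNA, rose by 1.10 ± 0.33 (SE, adjusted p = 0.025). The list median was 2.09 among F (adjusted p 1.49e-05) and 0.26 among M (adjusted p 0.338). The log2 difference of Mki67 was 2.48 among F and 0.35 among M libraries. Its call ended without Hom F 1 (adjusted p 0.0525), F 2 (adjusted p 0.0635) or F 4 (adjusted p 0.0637), and that of Top2a without Hom F 2 (adjusted p 0.0759), Hom F 4 (adjusted p 0.0789) or WT F 3 (adjusted p 0.0512). Of 8 mitochondrially encoded genes 2 rose (5 adjusted over the list alone), with a median of 0.68 (camera adjusted p = 0.00173, and adjusted p = 0.418 with an estimated correlation). The cytochrome oxidase subunit mt-Co1 rose by 0.90 ± 0.20 (SE, adjusted p = 0.0062) and mt-Cytb by 0.72 ± 0.22 (SE, adjusted p = 0.0395). The mean mitochondrial share of the libraries was 34.2% in Hom against 25.1% in WT among F, and 52.0% against 40.5% among M. The mt-Cytb call ended without any single library except Hom F 1, Hom M 4, WT M 4 and WT F 4 (adjusted p 0.0569 to 0.0798).

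The other sinoatrial node lists did not pass with all libraries together. Oxidative phosphorylation, fatty acid oxidation and white adipocyte markers passed within each letter, in opposite directions, with the preset correlation alone, and the difference between letters was not tested for lists. The correlation estimated over all libraries was 0.731 for oxidative phosphorylation and 0.555 for white adipocyte markers, far above the preset 0.01. Their medians were −0.34, −0.30 and 1.23 among F (adjusted p 1.71e-05, 0.000974 and 0.0266) and 0.30, 0.22 and −1.68 among M (adjusted p 7.94e-07, 0.000556 and 0.00387). Extracellular matrix (0.20, adjusted p 0.0179), immediate early (0.20, adjusted p 0.0424), interferon (−0.64, adjusted p 0.00312) and ion channel genes (−0.31, adjusted p 0.0113) passed among F. Of 26 extracellular matrix genes 5 rose and 1 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.137), with the short-chain collagen Col8a1 at 0.91 ± 0.13 (SE, adjusted p = 4.69e-05). Of 33 ion channel and calcium genes 3 rose and 7 fell (5 and 10 adjusted over the list alone, adjusted p 0.678), and Cacna1h, a T-type calcium channel, fell by 0.64 ± 0.14 (SE, adjusted p = 0.00243). Of 8 fibroblast markers 3 rose and 2 fell (4 and 2 adjusted over the list alone, adjusted p 0.437). The microfibril protein Mfap5 rose by 0.55 ± 0.09 (SE, adjusted p = 0.000133), and the receptor Pdgfra fell by 0.46 ± 0.09 (SE, adjusted p = 0.00168). Of 13 genes reported for Pitx2, 2 rose and 2 fell (2 and 2 adjusted over the list alone, adjusted p 0.557). Of 14 circadian genes 2 rose and 1 fell (2 and 1 adjusted over the list alone, adjusted p 0.715), and the 1 that fell was Nr1d1 at −0.39 ± 0.08 (SE, adjusted p = 0.00239). Of 14 interferon genes 1 fell (3 adjusted over the list alone, adjusted p 0.207), Stat1, at −0.46 ± 0.12 (SE, adjusted p = 0.0106). Of 15 immediate early genes (adjusted p 0.678) and 19 oxidative phosphorylation genes (adjusted p 0.849) 1 rose and 1 fell, as they did adjusted over the list alone. Of 19 fatty acid oxidation genes 1 rose and 1 fell (0 adjusted over the list alone, adjusted p 0.995). Of 7 macrophage markers (adjusted p 0.755) and 5 white adipocyte markers (adjusted p 0.849) limma called 0 (0 adjusted over the list alone), each with 1 at an unadjusted p under 0.05. edgeR called 0 in both, and DESeq2 called 1 macrophage marker and 0 adipocyte markers. Medians and means differed in sign for the genes reported for Pitx2, oxidative phosphorylation, fatty acid oxidation and macrophage markers here, median and test for circadian genes, and for fibroblast markers in right atrium, all within 0.07 of 0. Lists with under 5 tested members were not run. Of these, erythroid markers had 1 of 3 that rose and 1 that fell, skeletal muscle 2 of 4 and 1, and ventricle 1 of 4 and 1. Brown adipocyte (3 tested) and cartilage (2) had 1 that rose. Lung (2) and lymphocyte (4) markers had 0 by limma, edgeR and DESeq2, with 0 at an unadjusted p under 0.05.

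**Figure D4:**
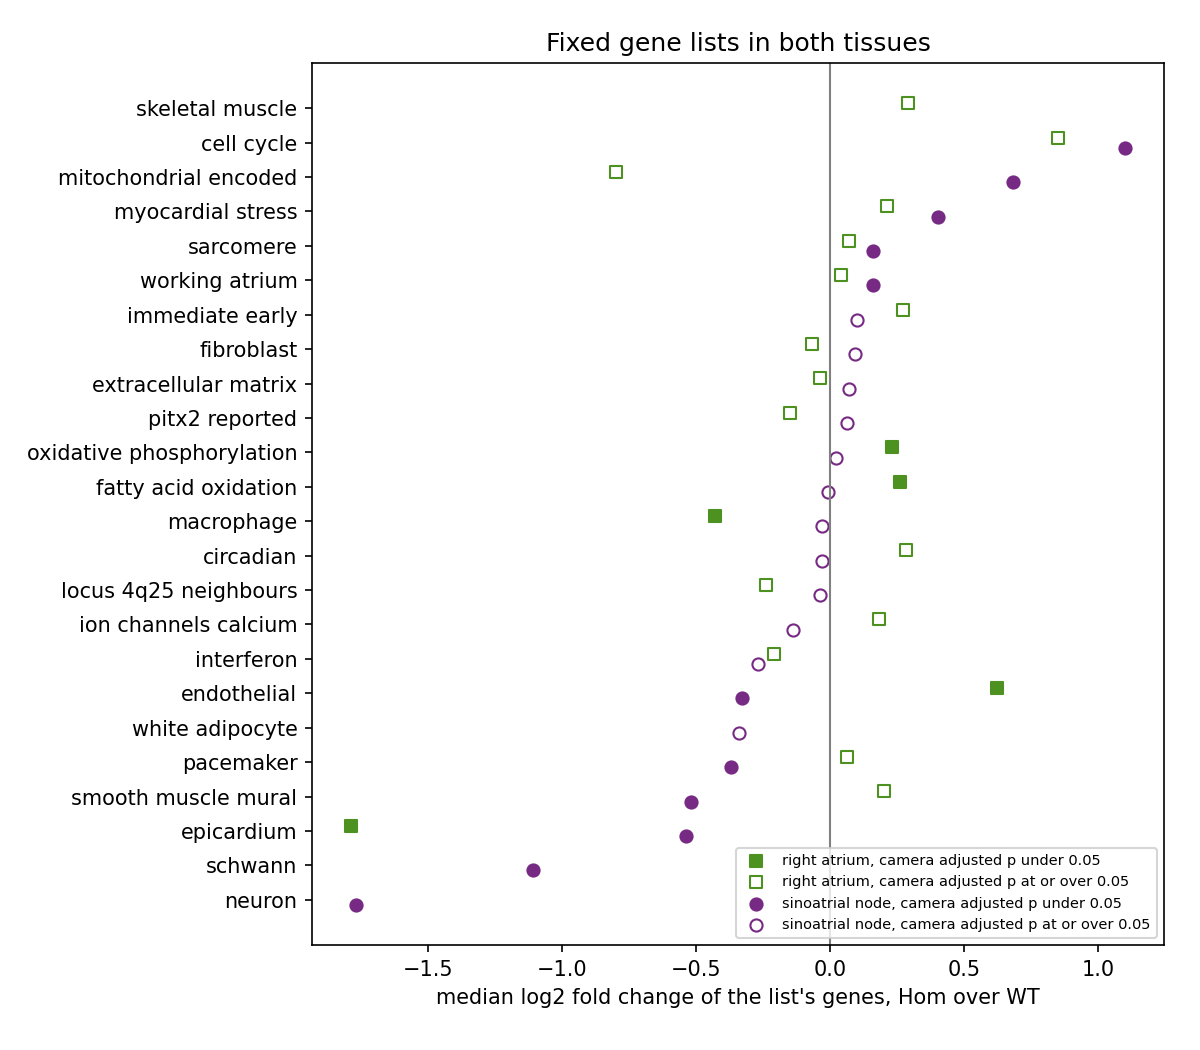
Median log2 of Hom over WT for each gene list on the horizontal axis, for right atrium and sinoatrial node, with filled points for lists past the camera threshold. The epicardium list lies at −1.79 in right atrium and −0.54 in sinoatrial node, and the neuron list at −1.77 in sinoatrial node.

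Across the sinoatrial node 880 genes rose and 1076 fell, 1956 of 13300 tested. Among the largest rises were Gipr, a receptor for an incretin hormone, at 1.95 ± 0.34 (SE, adjusted p = 0.00042 by limma), and the metalloproteinase Adamts8 at 1.48 ± 0.16 (SE, adjusted p = 8.75e-07). Inhba, a subunit of activin, rose by 1.27 ± 0.15 (SE, adjusted p = 3.6e-06). The largest falls included the amino acid transporter Slc7a14, which fell by 4.88 ± 0.75 (SE, adjusted p = 0.000129). Among F libraries alone Slc7a14 was at −2.86 and did not pass (adjusted p 0.0538). With any single library left out the count ran from 1565 to 1979.

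The tissues were compared to see whether the deletion acted alike in both. Genes past the threshold in both numbered 34 of 12512, with 8 that rose in both, 18 that fell in both and 8 that moved in opposite directions. Chance would give 15.5 (odds ratio 2.8, Fisher's exact test p = 4.77e-06). Ckmt1, Inmt and the epicardial markers Krt19 and Upk3b fell in both, Klf2 rose in both, and Hbb-bs rose in right atrium and fell in sinoatrial node. Across all genes the fold changes had Pearson's r = 0 and Spearman's rho = −0.02, and genes are not independent replicates. The test of the difference itself passed for 1000 genes, 538 with a higher effect in the node and 462 with a lower effect. Bmp10 differed by 1.57 and Lrrn4, at −2.23 in right atrium and −0.11 in the node, by 2.12 ± 0.32 (SE, adjusted p = 0.000272). Without the 4 right atrium libraries with over 75% mitochondrial reads the difference passed for 114 genes, 67 of them among the 1000. Of the 10 genes that the naming rule took for this difference, 8 then lost the call, and Bmp10 was at 0.54 in right atrium. Genes past the threshold in both tissues then numbered 287, of which 110 rose in both, 149 fell in both and 28 were opposite (146.3 by chance), with r = 0.3 and rho = 0.3 across all genes. Without WT right atrium F 1, 884 genes differed between tissues.

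Genotype effects also differed between letters. In the right atrium the difference between M and F passed for 2323 genes, 1238 with a higher effect among M and 1085 with a lower one. The mitochondrial gene mt-Nd5 was at −3.17 among F and 1.41 among M libraries, a difference of 4.58 ± 0.63 (SE, adjusted p = 0.000159). The WT F libraries of this comparison all had over 75% mitochondrial reads, so letter and mitochondrial share cannot be separated there. The median difference over all tested genes was −0.21. For the sinoatrial node 454 genes passed, 252 higher and 202 lower among M. The largest difference among the genes that the naming rule took was that of Chrna3, a nicotinic receptor subunit, at 0.07 among F and −8.23 among M libraries (adjusted p = 0.000546).

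The authors' deposited tables list 611 genes for right atrium (279 higher, 332 lower) and 2141 for sinoatrial node (977 higher, 1164 lower). All 106 right atrium calls and 1864 of the 1956 sinoatrial node calls of the limma fit are in them, each with the same sign. Sizes were not compared over all genes. The authors' node values were smaller than those above for Pitx2 (1.04), Snap25 (−0.89), Isl1 (−0.56) and Hcn4 (−0.63). They were close for Tbx3 (−0.59) and Myh7 (0.84).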

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

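Tests chosen only after a result was seen were those without 4 right atrium libraries, of Isl1 among F libraries, of the pacemaker list and of single pacemaker genes among F libraries, of Tbx3 in right atrium, and all tests of dilution except that of node-enriched genes. The splits of the libraries were set beforehand, and the tests of ganglion genes and node-enriched genes were set after the falls of neuron and pacemaker genes were seen but before their own values. Cpne5 was named after its value was seen.

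Single libraries stood apart from their group for 7 of 59 measures tested, where chance gives about 1 in 20 groups, or 3. WT right atrium F 2 was above the other 5 WT libraries for Hcn4 (normalised count 32.2), Hcn1 (45.1) and Isl1 (6.44), which are 10, 14 and 2 reads in a library where 1 read counts as 3.219, so the Isl1 value says nothing of the library, as WT M 5 had 4 reads. Hom right atrium F 7 was the lowest for Shox2 (5.95). Hom right atrium F 3 was at 1.15 for Hcn4 and F 7 at 0.743 for Isl1, which are 3 reads and 1 read, and where the other 5 libraries are at 0 any read stands apart, so these 2 say nothing of the library. WT sinoatrial node F 1 was above the others for Ryr2 (17082).

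The genotype effect differed between tissues for 1000 genes by the test of the difference, taken as sinoatrial node minus right atrium. Among named genes the effect was higher in the node for Acvr2b (2.75), Lmbrd2 (2.15), Lrrn4 (2.12), Sema3c (2.1), Ccdc15 (2.03), Bmp10 (1.57) and Ryr2 (0.87). It was lower in the node for Myo19 (−2.3), F5 (−2.45), Snca (−2.6), Lrrc16b (−2.95) and Whrn (−3.4). The Lmbrd2 call ended without WT right atrium F 1 (adjusted p 0.0744). Of the 10 genes other than Bmp10 and Ryr2, 8 lost the call without the 4 right atrium libraries with over 75% mitochondrial reads. Without the letter term 7 of the 10 did. Without those 4 libraries Bmp10 and Ryr2 were at 0.54 and 0.41 in right atrium. Of 100 splits of the libraries, 2 gave as many genes, the real split with 1000 included, and the highest other gave 1192. The splits shuffled genotype in both tissues, so they test against no genotype effect in either. An effect in 1 tissue alone also fills this count, as the split with 1192 had 1212 genes in right atrium and 0 in the node. The splits thus cannot show that the effects differ between tissues. For the 34 genes past the threshold in both tissues 1 of 100 splits gave as many and the highest other gave 0, but in 98 of the 99 other splits right atrium had 0 genes and in the last the node had 0, so this says nothing of the overlap.

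The effect differed between letters for 2323 genes in right atrium, taken as M minus F. Named genes were Lars2 (4.66), mt-Nd5 (4.58), mt-Nd2 (4.58), Lmbrd2 (4.47), mt-Nd6 (4.36), Bmp10 (2.74), Ryr2 (1.85), Gja1 (1.8), Dok7 (−4.67), Tmem198b (−4.95), Lrrc16b (−5.03), Gtpbp6 (−5.13) and Tmem200b (−5.63). For the sinoatrial node it was 454 genes. There the named genes were Chgb (3.48), Mmp9 (2.63), Ifit1 (2.43), Grin2c (2.31), Opn4 (1.8), Gja5 (1.19), Isl1 (−5.18), Odz2 (−6.95), Tubb3 (−7.09), Npy (−7.74), Nefm (−8.24) and Chrna3 (−8.3). Of 100 splits 1 gave as many as 2323 in right atrium, with 1835 in the highest other. Among sinoatrial node splits 2 gave as many as 454, with 1094 in the highest other. These splits shuffled genotype within each letter, so they test against no genotype effect at all. Both counts were beyond that at 0.05, which cannot show that the effects differ between letters. A split that keeps the genotypes of 1 letter and swaps those of the other turns a genotype effect into such a difference. Whether the 1094 genes of a split other than the real one come from a structure of the samples was thus not settled.

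For the genotype effect itself, 1 of 100 splits gave as many as the 1956 genes of the sinoatrial node, with 231 in the highest other. In right atrium 2 gave as many as the 106 genes. The highest other gave 1212, which points to a structure of the samples. It put all 4 libraries with over 75% mitochondrial reads on the same side, but the 10 splits that did so had a median count of 0, so that alone did not give the count. For the gene lists chance was not excluded. In right atrium 14 of 100 splits gave as many as 5 lists, with 10 in the highest other, and in the sinoatrial node 5 gave as many as 11, with 12 in the highest other.

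The difference between tissues may come in large part from the 4 right atrium libraries with over 75% mitochondrial reads. Without them 114 genes differed, against 153 to 4083 (median 847) for the 119 other sets of 3 WT and 1 Hom libraries. The 2 other sets that also left 2 Hom M against 3 WT M libraries gave 284 and 515. The 5 sets that left out none of the 4 left out all 3 WT M libraries and gave 3173 to 3845 genes. Their right atrium effect compares Hom F with the 3 WT F libraries alone, all over 75%, so these counts decide nothing. A difference of biology between right atrium and node stays open, since 114 genes still passed and the remaining WT right atrium libraries were all M.

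The fall of neuron markers and Isl1 in the sinoatrial node may reflect autonomic ganglion tissue in the 4 WT M libraries. The added ganglion genes (6 tested of 14, of which 5 are also in the fixed neuron list and 2 of those were tested) had a median of −2.27 among M libraries, where all 6 fell, and 0.11 among F libraries. The most abundant, Uchl1 and Stmn2, had mean normalised counts of 1809 and 1456 in WT M, 251 and 205 in WT F, and 495 and 301 in Hom M. Isl1, which autonomic neurons also express, was at −0.19 ± 0.67 (SE) among F libraries and −5.36 among M. Both values are consistent with ganglion tissue that was present in unequal amounts, which leaves without an account the falls of Ngfr and Sox10 among F libraries (−1.75 and −0.69, adjusted p 0.0192 and 0.0421) and that of the granin gene Chgb, at −5.08 among F and −1.60 among M, while a loss of nerve tissue with genotype in M alone was not tested.

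The fall of pacemaker genes in the sinoatrial node could come from more right atrial tissue in the Hom dissections, from ganglion tissue in WT M libraries, or from the node itself. Full replacement by atrial tissue would put Cacna2d2 (−0.48 ± 0.10, SE) at 0.89 ± 0.16 and Cpne5 (−0.36 ± 0.12, SE) at 0.12 ± 0.16 (SE of the ratio). The tissue ratio was taken over the median ratio of all genes and from libraries of both genotypes. Hom libraries lower the ratio of a gene that falls in Hom and so raise its value for full replacement. Dilution is thus argued against for 1 of the 8 genes that fell, Cacna2d2, while Cpne5 lies too near its value to decide. For the others, Tbx3 (−0.63 against −1.08) among them, dilution stays open. The 104 genes at least 8-fold higher in the node table had medians of −0.15 among F (SE 0.11, a spread taken into account after the value was seen) and −0.93 among M. The 6 called genes below that enrichment differed from those 104 by −0.34 among F (permutation p = 0.114) and by 0.52 among M (permutation p = 0.0286, the smallest it can give). The second would go with dilution, but the 104 genes include Isl1, which may fall among M through ganglion tissue in WT M libraries. This value thus cannot tell dilution from ganglion tissue. The 11 right atrium-enriched genes, which dilution would raise, were at −0.61 among F (SE 0.48) and −0.12 among M (SE 0.30), Bmp10, higher in the right atrium table, at 0.93 ± 0.28 (SE) and 0.88 ± 0.14 (SE), and the node-enriched Shox2 at 0.42 ± 0.19 (SE) and −0.24 ± 0.19 (SE), which point both ways, and the 3 called genes under 2-fold enrichment in the deposited tables and Tbx3 in right atrium (−1.31 without the 4 libraries) decide nothing. Ganglion tissue in WT M is argued against for 3 of the 8, Cacna1g, Cacna2d2 and Cpne5, which also passed among F libraries (−0.53, −0.60 and −0.58, adjusted p 0.0258, 0.0158 and 0.00961), and stays open for the other 5, since the list did not pass among the 7 F libraries (median −0.25, adjusted p = 0.118) and passed among M (median −0.39). Nerve tissue in unequal amounts among F libraries was not excluded for these 3. Ngfr and Sox10 fell among F, though the added ganglion genes had a median of 0.11 there.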

How the results depend on the processing

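Alternatives chosen after the data were seen were those without the 4 libraries with over 75% mitochondrial reads, without the 3 WT F libraries, with the mitochondrial share as a covariate, and of lists within a letter. The cause of a change was not tested unless stated. Apart from leaving out a library, 38 counts stayed within 1.5 times and 23 moved. Values of named genes kept direction and call 1317 times, lost the call 160 times, gained it 35 times and changed sign 30 times.

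In right atrium the 106 genes became 56 without the letter, 688 by DESeq2, 608 with library weights, 2422 among F alone, 512 with the mitochondrial share, 998 without the 4 libraries and 370 without the 3 WT F libraries. Leaving out each library gave 39 to 311. The 5 lists became 0 with an estimated correlation, 14 by fry (mixed), 12 among M alone and 10 without the 4 libraries. Signs turned for Bmp10, Ryr2, Gja1 and Gja5, in this order, to 0.23, 0.2, 0.03 and 0.07 with library weights. They were 0.7, 0.48, 0.34 and 0.08 among M alone and without the 3 WT F libraries, and 0.54, 0.41, 0.19 and 0.18 without the 4 libraries. Shox2 was at −0.4 among F alone.

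For the sinoatrial node the 1956 genes became 1284 without the letter, 916 among M alone, against 1558 among F alone, and 3393 with the mitochondrial share. Leaving out each library gave 1565 to 1979. The 11 lists became 4 with an estimated correlation and 18 by fry (mixed). Hcn1 turned to 0.12 with library weights and 0.08 among F alone, Prph to 0.18 and Gja1 to −0.01 among F alone, and Gja5 to 0.34 and Shox2 to −0.24 among M alone. Leaving out each library gave −0.02 to 0.17 for Shox2, −0.35 to 0.05 for Hcn1 and −0.02 to 0.08 for Gja1. With the mitochondrial share Gja1 was at −0.15 and Shox2 at −0.17. The working atrium list pointed down among F alone (adjusted p = 0.0925).

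The 1000 genes that differed between tissues became 417 without the letter and 114 without the 4 libraries. The right atrium test of Pitx2 rested on 8 reads in all. The 34 shared genes became 80 at an adjusted p of 0.1 and 287 without the 4 libraries.

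Title numbers were not shown to pair libraries, since 7 pairs across genotypes correlated between −0.12 and 0.08. With letter and number as a replicate block, right atrium gave 2076 genes and 12 lists, from the 2 pairs M 1 and M 5 alone, the Hom M libraries behind the set without the 4, with Bmp10 at 0.54, Ryr2 at 0.41, Gja1 at 0.13 and Gja5 at 0.24. The sinoatrial node gave 410 genes, with Gja1 at −0.05 and Pitx2 at 2.67 (adjusted p = 0.0724).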

Other observations

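The MHC class II and heat shock lists were chosen and tested only after the results had been seen, and so was the set without 4 right atrium libraries. Genes of MHC class II, which present antigen on immune cells, were lower in the sinoatrial node of Hom. H2-Aa fell by 1.24, the invariant chain Cd74 by 0.97 and H2-Ab1 by 0.97, with adjusted p of 6.51e-07, 3.32e-06 and 0.000104 by limma. These were the 3 of 7 that fell, and the list median was −0.97 (camera adjusted p = 8.31e-05, and adjusted p = 0.0435 with an estimated correlation). Within a letter the node list passed among M (median −1.28, adjusted p = 2.9e-06, and adjusted p = 0.0131 with an estimated correlation) and did not pass among F (median −0.45, adjusted p = 0.105). In right atrium limma called 0 of the 7 with all libraries (median −0.07, adjusted p = 0.909), with medians of 1.22 among F (adjusted p = 0.0548) and −1.26 among M (adjusted p = 2.63e-08, and adjusted p = 0.066 with an estimated correlation). Without the 4 libraries with over 75% mitochondrial reads, which leaves 2 Hom M against 3 WT M libraries for the fold changes, 6 of the 7 fell there (median −1.04, adjusted p = 1.45e-09, and adjusted p = 0.0041 with an estimated correlation).

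Heat shock genes, whose products help proteins to fold, rose in right atrium as a list. Hsph1 at 0.97 and Hspa8 at 0.70 were the 2 of 15 that rose, and the median was 0.36 (camera adjusted p = 3.46e-05, and adjusted p = 0.00343 with an estimated correlation). Within a letter the right atrium list did not pass among F (median 0.66, adjusted p = 0.0591), and among M it passed (median 0.40, adjusted p = 1.14e-06) but not with an estimated correlation (adjusted p = 0.066). In the sinoatrial node 2 rose and 3 fell (median −0.09, adjusted p = 0.241), and Hspa8 fell by 0.42 (adjusted p = 0.00498). Among F libraries of the node 5 fell and 1 rose, and the list passed downwards (median −0.31, adjusted p = 0.000197, and adjusted p = 0.024 with an estimated correlation). The ganglion neuron genes had 4 of 6 that fell in the sinoatrial node over all libraries (median −1.27, camera adjusted p = 8.13e-05, and adjusted p = 0.093 with an estimated correlation). In right atrium limma called 0 of the 3 tested (adjusted p = 0.944).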
